A study of Mus musculus with 32 samples.

How the data were processed

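RNA of 4 tissues (brain, kidney, muscle and pancreas) from male Nox4 knockout mice (C57BL/6, aged 17 weeks) was measured on cDNA microarrays, per the labels. Each of 4 knockout animals gave all 4 tissues. Every tissue sample was hybridised on 2 arrays with the dyes exchanged, against RNA pooled from wild-type males of the same age and strain. The design text and the labels of the second channel give 4 wild-type animals for this pool, and the labelling protocol gives 6 control animals, so its size is not settled. Per the labels' protocols, 20 µg of total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5.

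The deposited values are log2 ratios, 1 per probe and array. The authors' tables do not name the base of the logarithm; base 2 was inferred from the size of the values at the floor, which reach 17.2. Scanner, background correction, normalisation and filters are not given in the sources used here. Array medians lay between −0.07 and 0.05. Arrays carried 19815 to 20684 values of 20794 probes. Values beyond 8 in size (1844 of 655162, or 0.282%) stood apart from all others, with 0 values between 8 and 15. They were positive only on arrays with the knockout in Cy5 (920) and negative only on arrays with the knockout in Cy3 (924). They were kept as deposited in the reported tests and taken as missing in an alternative. Signal over background was not used here, and the number of arrays limits the precision of every value.

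A probe annotation table gave 12771 probes 1 gene symbol, 0 probes several and 8023 probes none. All 9030 symbols were found in the RefSeq gene table of assembly GRCm38.p6, which served for names and for the genes neighbouring Nox4 only. The files name no build, so no coordinates are given. Probes of the same symbol (2754 symbols had more than 1) were averaged, and a probe without a symbol stayed a unit of its own and was never named, which left at most 17053 units, called genes here.

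The direction of the ratios is likely knockout over wild-type pool, from the design text and the channel that holds each sample's own RNA. If it is the inverse, higher and lower swap throughout. Whether ratios of the dye-swapped arrays had already been turned was tested by a rule fixed before the data were examined. The rule asked whether the residuals of an animal's 2 arrays correlate better than those of different animals. With floor values left out, a step the rule as fixed did not have, they did so in 6 of 16 animal and tissue combinations. They correlated less well in 10. With floor values kept, as the rule was fixed, they correlated better in only 3 of 16. By either count the rule would turn the Cy3 arrays, without floor values by a bare majority. The count of 6 was taken as undecided and the signs were kept, which departs from the rule as fixed. Results with the Cy3 arrays turned are given as well. Arrays of the same dye orientation in a tissue correlated at r from 0.0368 to 0.563 across probes. The 2 arrays of an animal correlated at r from −0.642 to 0.112.

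The 2 arrays of an animal were averaged to 1 value, which cancels a dye effect of a probe if all ratios run the same way, and both arrays were required. Within a tissue, limma (version 3.58.1, R 4.3.3) tested the mean over animals against 0 with lmFit and eBayes, two-sided, for genes with at least 3 animals. The Benjamini-Hochberg adjusted p threshold was 0.05. The pool counts as 1 control sample, so the test leaves out the spread between wild-type animals. Standard errors (SE) are those of limma, after moderation; SD is the plain spread between animals. Between tissues, limma fitted all 4 tissues at once with a shared spread and tested each of the 6 differences, with 12 residual degrees of freedom.

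For gene groups, 39 lists were fixed before the data were examined: 15 of processes, 1 of genes near Nox4 and 23 of cell type markers, with 1014 entries, of which 667 were on the array. They were tested with camera of limma at a preset correlation of 0.01, for lists with at least 5 measured genes, and again with an estimated correlation and with fry. The rule for named genes, also fixed beforehand, took every called gene of a tissue up to 24. With fewer than 10 calls it added the 8 higher and 8 lower genes of smallest p with the same sign in all 4 animals and in both dye orientations, as values only. It further took up to 2 members of a list that did not pass and the 5 genes of smallest p in each direction for each pair of tissues with calls.

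The animal numbers pair the tissues, because the labels give the same animals. The deviations of an animal from the mean of its tissue correlated between tissues at r from −0.0970 to 0.123. Alternatives were centred or scaled arrays, probes taken singly, other rules for missing arrays, an 8-array fit with a dye term, each dye orientation alone, turned signs, each animal left out, the animal as a block, other choices of tissues in the fit and robust moderation. Floor values as missing, weights for the spread of each tissue and the loss of 1 brain array were added after seeing the data.

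The code was tested on simulated data, drawn as independent normal values with the moderated spreads of limma and without floor values. Many genes were changed in each tissue, which eases the adjusted p threshold. The shares recovered therefore do not give the power of the tests on the real data. Changes of log2 1 were recovered for 100% of genes in brain, 98.5% in kidney, 98.5% in muscle and 95.5% in pancreas. At log2 0.5 the shares were 83.6%, 98.5%, 49.3% and 23.9%. In every tissue camera called a simulated list of 30 genes moved by 0.3 and 0 of the unmoved lists. For muscle against pancreas, 103 of 273 simulated calls were false, against 13 of 151 when only these 2 tissues were fitted. In the fit of all tissues with no gene changed there were 32 false calls for this pair, against 1 for brain against muscle and 0 for kidney against muscle. The same fit tested within a tissue gave 2 false calls in brain, 0 in kidney, 18 in muscle and 203 in pancreas. Each count is 1 draw with independent genes and does not show how far counts vary when genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.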

Results

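Nox4 encodes an NADPH oxidase that produces hydrogen peroxide, and the study asked how its loss alters transcript levels in brain, kidney, muscle and pancreas. The data are 32 arrays: in each tissue 4 knockout animals, each on 2 dye-swapped arrays, against a pool of wild-type RNA. Brain arrays carried 20280 to 20607 values, kidney arrays 20621 to 20684, muscle arrays 20183 to 20650 and pancreas arrays 19815 to 20525. The median SD between animals was 0.13 in brain, 0.10 in kidney, 0.17 in muscle and 0.22 in pancreas on the log2 scale.

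No probe on the array is named Nox4 (0 of 20794), so the targeted transcript gives no check of the labels or of the direction of the ratios. Values are log2 ratios that likely run knockout over pool. Of its relatives, Rac2, a GTPase that takes part in the phagocyte NADPH oxidase, had a mean log2 ratio of −0.36 ± 0.07 (SE, n = 4) in muscle and −0.36 ± 0.10 (SE, n = 4) in kidney, below 0 in every animal of both tissues. Adjusted over the list alone, the 8 measured genes of the NADPH oxidase family, Rac2 passed in muscle (limma, adjusted p = 0.0251) and not in kidney (limma, adjusted p = 0.0968). With each list adjusted by itself, chance alone would give such a call in about 7.8 of the 156 combinations of list and tissue, and 11 held 1. Cybb, the catalytic subunit of the phagocyte enzyme, was at 0.43 ± 0.19 in muscle and above 0 in 3 of 4 animals. Noxa1, which activates Nox1, was at −0.46 ± 0.20 in pancreas, −0.47 ± 0.22 in muscle and 0.50 ± 0.23 in kidney, with 3 of 4 animals on that side in each, and Noxo1, another Nox1 partner, at 0.12 ± 0.06 in brain. The family as a group had a median of −0.10 in muscle, −0.05 in pancreas, −0.02 in kidney and 0.01 in brain, and passed camera in none of the 4 tissues.

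In brain, Gtf2f2, a subunit of the general transcription factor TFIIF, had the smallest p of the genes above the pool, at 0.49 ± 0.04 (SE, n = 4), above 0 in all 4 animals but on only 5 of 8 arrays. Sec23b, part of the COPII vesicle coat, was at 0.26 ± 0.05, and Cdyl, a chromodomain corepressor, at 0.44 ± 0.10. Below the pool lay Otx1, a homeobox factor of cortical development, at −0.33 ± 0.05, and Pkig, an inhibitor of protein kinase A, at −0.24 ± 0.04, both on all 8 arrays. Alas2, the erythroid enzyme that starts haem synthesis, was at −0.23 ± 0.05, the heparan sulphate proteoglycan Gpc3 at −0.36 ± 0.08 and the interferon-induced chemokine Cxcl9 at −0.27 ± 0.06, likewise on all 8 arrays. Of the other genes taken by the rule, Cdca8, Ing2, Prap1, Rbl1 and Kank2 lay between 0.18 and 0.28, Rsl24d1 at −0.18 and the lipoxygenase Alox12e at −0.74 ± 0.16. Asap1 stood at −2.17 ± 0.46, with floor values on 1 of its 3 probes, and at −0.10 with floor values as missing. None of these passed: limma called 0 of 16729 genes in brain (smallest adjusted p = 0.773), with 691 at an unadjusted p under 0.05 where chance gives 836.4. Without animal 2 the count was 1, Asap1, and with the Cy3 arrays turned it was 1, Ppm1b, with floor values on 4 of 8 arrays.

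In kidney Hikeshi, which carries HSP70 into the nucleus under heat stress and lies near Nox4 on its chromosome, was at −0.35 ± 0.04 (SE, n = 4), below the pool on all 8 arrays. Hba-x, an embryonic globin, was at −0.40 ± 0.05 and Cmss1 at −0.37 ± 0.05, also on all 8. Cd82, a tetraspanin, was at −0.31 ± 0.05, the ephrin receptor Epha4 at −0.32 ± 0.05, and Plcb1, Echdc3 and Tpgs1 between −0.25 and −0.24. Above the pool were Lepr, the leptin receptor, at 0.27 ± 0.04, Snx3, an endosomal sorting protein, at 0.31 ± 0.06, and Pln, the inhibitor of the sarcoplasmic calcium pump, at 0.60 ± 0.13 (above 0 on 5 of 8 arrays). Apool, Fjx1, Cdipt, Pfn3 and Adamts5 lay between 0.18 and 0.25. Stk32b, a kinase named after its values were seen because it had the smallest p, was at 1.19 ± 0.06 in the 3 animals measured (limma, adjusted p = 0.127). Limma called 0 of 16825 genes, with 1562 at an unadjusted p under 0.05 where chance gives 841.2, and 0 with the Cy3 arrays turned. An 8-array fit with a dye term called 7, which were Hikeshi, Hba-x, Cmss1, Lcn8 and 3 probes without a name. Lcn8 was at 8.57, with floor values on 2 of its 6 arrays, and was named after its value was seen. This fit took the 2 arrays of a kidney animal as correlated at −0.28. A negative value makes the SE smaller than that of 8 independent arrays, so the 7 calls rest in part on it. Both robust moderation and floor values as missing called Stk32b alone.

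Among members of the lists in kidney, Slc22a6, the organic anion transporter OAT1 of the proximal tubule, was at −0.33 ± 0.05 (SE, n = 4), Slc22a7, a related transporter placed among the androgen-dependent genes, at −0.17 ± 0.04, and the chloride channel Cftr at −0.28 ± 0.06, each below 0 in all 4 animals. Adjusted over the list alone, all 3 passed (limma, adjusted p = 0.0119, 0.0398 and 0.0278), as did Hikeshi among the 22 genes near Nox4 (adjusted p = 0.00365); over all genes none did. Of 16 proximal tubule genes 10 were below 0, with a median of −0.03. The chaperones and genes of the unfolded protein response leaned lower, 22 of 30 below 0 with a median of −0.04, led by the HSP40 co-chaperone Dnajb1 at −0.23 ± 0.05 and the transcription factor Xbp1 at −0.16 ± 0.05. This list did not pass (camera of limma, adjusted p = 0.357, and adjusted p = 0.948 with an estimated correlation). Among antioxidant enzymes Prdx1, a peroxiredoxin, was at −0.23 ± 0.05 and the extracellular superoxide dismutase Sod3 at 0.16 ± 0.04. Of the hypoxia genes, Ldha, lactate dehydrogenase, was at −0.37 ± 0.10 and Epas1, the HIF-2 alpha subunit, at −0.29 ± 0.08, in a list of 16 with a median of 0.00.

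In muscle the largest values among the genes taken by smallest p were above the pool. Man1c1, a Golgi mannosidase, was at 1.37 ± 0.13 (SE, n = 4), or 2.59-fold, and Psmd2, a subunit of the regulatory particle of the proteasome, at 1.10 ± 0.13, or 2.15-fold. Ppp1r15a, which directs a phosphatase to eIF2 alpha under stress, was at 0.49 ± 0.06, the cytokine Il18 at 0.53 ± 0.07, Unc13b, a vesicle priming protein, at 0.72 ± 0.11, Rpap1 at 1.29 ± 0.19, Gng10, a G protein gamma subunit, at 0.71 ± 0.11 and 2310030G06Rik at 1.13 ± 0.15, all on all 8 arrays. Below the pool lay Rac2, Lgals1, the lectin galectin-1, at −0.28 ± 0.06, Ttll6, a tubulin-modifying enzyme, at −0.31 ± 0.06, and Mau2, a loader of cohesin, at −0.80 ± 0.19. Ift81, Cyp2d12, Aplf and Crisp2 lay between −0.35 and −0.26. In total 251 genes lay above the pool on all 8 muscle arrays and 89 below, against 66 and 81 in brain, 93 and 150 in kidney and 15 and 22 in pancreas, and 28.3% of the 300 probes of the 251 carried numbers in the last 10% of the array's probe numbers. Limma called 0 of 16662 genes in muscle (smallest adjusted p = 0.539), with 1215 at an unadjusted p under 0.05 where chance gives 833.1. The count was 1 without animal 2 (Brd3, a gene with floor values), 2 in the 8-array fit (Man1c1, and Foxk1 at 9.38 with floor values on 2 of its 6 arrays), 255 in a fit that shares the spread of all 4 tissues (227 higher and 28 lower, where simulated data with no gene changed gave 18) and 328 with the Cy3 arrays turned (74 higher and 254 lower). The simulated count of 18 is 1 draw with independent genes, while the 251 genes had a median pairwise r of 0.554 over the 8 arrays. Setting 255 against 18 therefore does not measure an excess over chance. With the Cy3 arrays turned, 2063 genes instead of 340 had the same sign on all 8 muscle arrays, against 1156 in brain, 1030 in kidney and 3305 in pancreas.

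Of the gene groups in muscle, Ctss, the lysosomal protease cathepsin S, led the macrophage markers at −0.53 ± 0.08 (SE, n = 4), ahead of the complement gene C1qb at −0.14 ± 0.06. Tsc1, a brake on mTOR signalling, was at 0.41 ± 0.07 and Pik3ca, the catalytic subunit of PI3 kinase, at 0.24 ± 0.06. Ncam1, an adhesion molecule of denervated and regenerating fibres, was at 0.48 ± 0.10 and the stress gene Gadd45a at 0.35 ± 0.11. Adjusted over the list alone, Ctss, Tsc1 and Ncam1 passed (limma, adjusted p = 0.0142, 0.0320 and 0.0446), each with the same sign in all 4 animals; over all genes none did. Thbs1 and Lamb1, matrix glycoproteins, were at 1.02 ± 0.18 and 0.76 ± 0.20, while 19 of 33 matrix genes lay below 0. Gapdh was at 0.83 ± 0.19, with 7 of 14 glycolysis genes above 0, and the peroxide-degrading enzyme Cat at −0.29 ± 0.08. Of 55 ribosomal protein genes 39 were below 0, with a median of −0.06, and of 14 macrophage markers 9, with a median of −0.08; neither list passed (camera of limma, adjusted p = 0.658 for both, and adjusted p = 0.919 with an estimated correlation).

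In pancreas Best1, a chloride channel, was at 0.81 ± 0.11 (SE, n = 4), Fhod3, a formin of actin filaments, at 0.51 ± 0.08, Cox20, an assembly factor of cytochrome c oxidase, at 0.45 ± 0.07, and Cpt2, which brings fatty acids into mitochondrial oxidation, at 0.40 ± 0.09. Pomc, the precursor of ACTH, was at 0.51 ± 0.10, but it lay above 0 on 4 of 8 arrays and its mean was 0.82 with the knockout in Cy5 and 0.20 with the knockout in Cy3. Cd80, Extl1 and Spire1 lay between 0.43 and 0.62. Below the pool lay Cnn2, a calponin, at −0.61 ± 0.10 on all 8 arrays, Lcn2, a siderophore-binding protein of inflamed epithelia, at −0.48 ± 0.08 (below 0 on 5 of 8), Mrpl21, of the mitochondrial ribosome, at −0.56 ± 0.11 and Pygb, a glycogen phosphorylase, at −0.38 ± 0.08. Grpel1, Pigf, Clptm1 and H3c15 lay between −0.59 and −0.35. Adjusted over the list alone, Lcn2 passed among inflammation genes and Pomc among hypothalamic and pituitary genes (limma, adjusted p = 0.0396 and 0.0352). Gpx7, a glutathione peroxidase of the endoplasmic reticulum, was at −0.53 ± 0.14, and the hypoxia-induced hydroxylase Egln3 at −0.37 ± 0.08. Acinar markers had a median of 0.00 (7 of 15 above 0) and islet markers a median of 0.04 (8 of 11 above 0). Limma called 0 of 16377 genes in pancreas (smallest adjusted p = 0.991), with 477 at an unadjusted p under 0.05 where chance gives 818.8. The count was 57 in the fit that shares the spread of all 4 tissues (31 higher and 26 lower, where simulated data with no gene changed gave 203) and 2388 with the Cy3 arrays turned (1038 higher and 1350 lower).

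**Figure D1:**
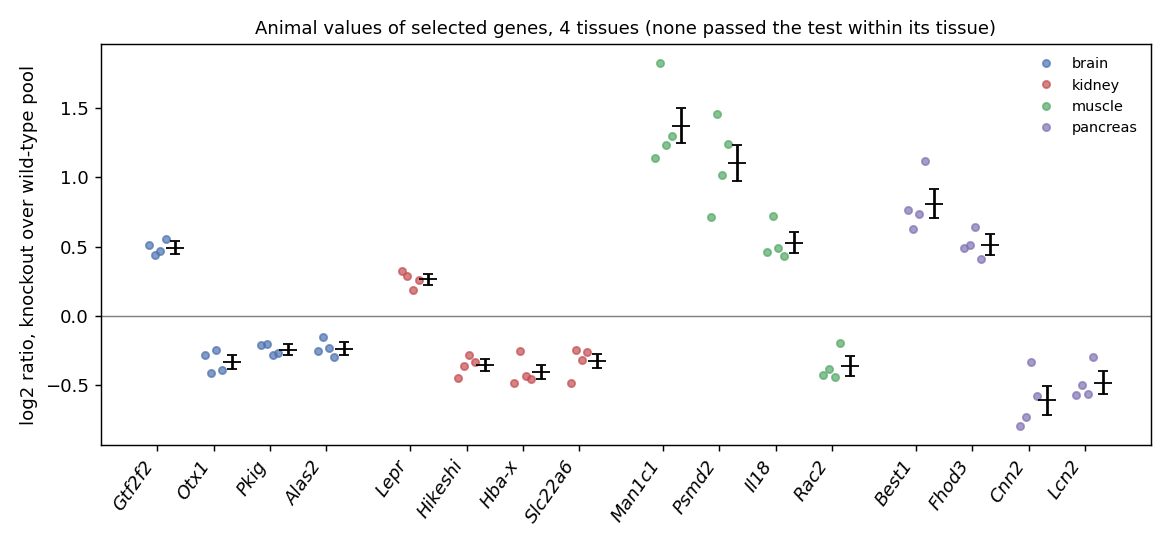
Log2 ratio (vertical axis, knockout over wild-type pool) of 4 genes in each of 4 tissues (horizontal axis). Points are the 4 animals, each the mean of 2 arrays, and bars are the mean with the SE of limma; Man1c1 in muscle (mean 1.37) stands farthest from 0, and every animal of a gene lies on the same side of 0.

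Among the 39 gene lists none passed the test. Camera called 0 of 151 combinations of list and tissue (3 at an unadjusted p under 0.05), with 0 calls at an estimated correlation, 0 with fry and 0 with the Cy3 arrays turned. List medians ran from −0.17 to 0.08. Over the list alone, 11 genes passed among 156 combinations, where chance gives about 7.8 combinations with a call: 1 in brain, 4 in kidney, 4 in muscle and 2 in pancreas, the brain gene being Alas2 (limma, adjusted p = 0.0141). The other 3 erythroid genes measured in brain lay above 0. The genes near Nox4 had 18 of 22 members above 0 in brain, with a median of 0.06 (camera of limma, adjusted p = 0.460, and adjusted p = 0.867 with an estimated correlation), led by Sytl2 at 0.12 ± 0.05 and Isg20 at 0.11 ± 0.05. In brain, 17 of 22 insulin signalling genes were above 0 with a median of 0.04, although Sos1, a RAS activator, was at −0.48 ± 0.12.

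The difference between tissues in the log2 ratio of knockout over pool was tested for 16257 genes. Higher or lower in a tissue here means a higher or lower ratio. It does not mean a higher or lower transcript level, since no array compared tissues. All animals of a tissue were set against the wild-type pool, so the SEs and calls leave out its deviation. Psmd2 was higher in muscle than in brain (difference brain minus muscle −1.21 ± 0.15, SE), than in kidney (kidney minus muscle −1.12 ± 0.15) and than in pancreas (muscle minus pancreas 1.04 ± 0.15), with limma adjusted p = 0.0207, 0.0343 and 0.0210. Man1c1 was higher in muscle than in brain (−1.39 ± 0.20) and pancreas (1.64 ± 0.20), and so was Ublcp1, a phosphatase of the proteasome (−1.36 ± 0.22 and 1.38 ± 0.22). 2310030G06Rik (−1.24 ± 0.19) and the transcription factor Trerf1 (−0.54 ± 0.09) were higher in muscle than in brain, and Ttll6 was lower (0.51 ± 0.10). Against pancreas, Cnn2 (1.12 ± 0.13) and the aspartyl protease Bace2 (1.58 ± 0.25) were higher in muscle; Best1 (−0.66 ± 0.11), Pomc (−0.63 ± 0.10), Homez (−0.74 ± 0.13), Tulp2 (−0.67 ± 0.11) and Tsen15, of the tRNA splicing endonuclease (−0.74 ± 0.13), were lower. Limma called 75 genes between brain and muscle, 73 of them higher in muscle, 2 between kidney and muscle and 94 between muscle and pancreas, 71 of them higher in muscle. It called 0 between brain and kidney, brain and pancreas, and kidney and pancreas, with 475, 1347 and 921 at an unadjusted p under 0.05 where chance gives 812.8.

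These counts moved with single animals and with the fit. With the animal as a block they were 0 for brain and muscle, 0 for kidney and muscle and 24 for muscle and pancreas, and all 3 were 0 when only the 2 tissues compared were fitted. Without animals 1, 2, 3 and 4 in turn they were 223, 0, 1 and 0 for brain and muscle, 44, 0, 0 and 0 for kidney and muscle, and 115, 1, 2 and 3 for muscle and pancreas. Without animal 3 there was 1 call between brain and kidney and there were 2 between brain and pancreas; without animal 4 there were 7 between brain and pancreas and 3 between kidney and pancreas. With the Cy3 arrays turned the counts were 1, 0 and 5 for the pairs with muscle, 0 for brain and kidney, 1510 for brain and pancreas and 355 for kidney and pancreas. The 94 rest on a shared spread that in simulated data made 32 calls with no gene changed, and weights for the spread of each tissue left 0 of them.

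**Figure D2:**
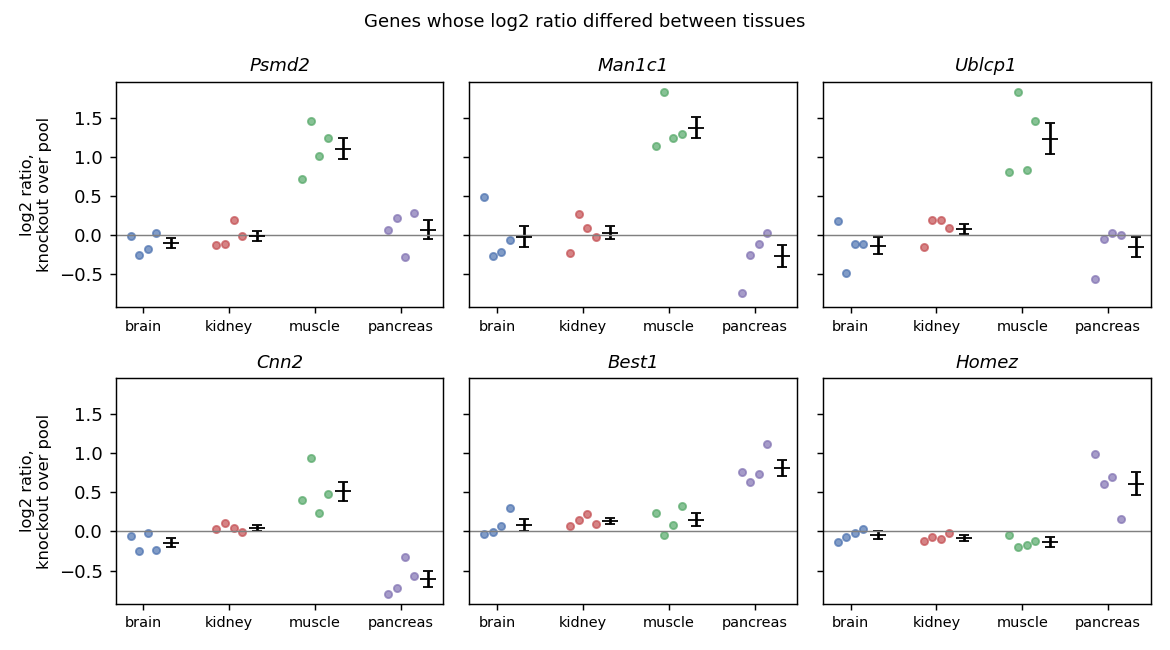
Log2 ratio (vertical axis, knockout over wild-type pool) of 6 genes in 4 tissues (horizontal axis). Points are the 4 animals, each the mean of 2 arrays, and bars are the mean with the SE of limma; Psmd2 averages 1.10 in muscle against −0.10 in brain, −0.02 in kidney and 0.07 in pancreas.

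Mean log2 ratios of different tissues were nearly unrelated across genes. Pearson r over 16257 genes was 0.0125 for brain and kidney, −0.0655 for brain and muscle, −0.0202 for brain and pancreas, 0.0551 for kidney and muscle, −0.00346 for kidney and pancreas and −0.0640 for muscle and pancreas. Spearman rho ran from −0.107 to 0.0949. Genes are not independent replicates, and no p is given. With the Cy3 arrays turned, r was 0.453, 0.352, 0.305, 0.530, 0.528 and 0.530 in the same order.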

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

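The tests of tissue differences and the splits of the animals were set before their results were seen; leaving out the brain array of widest spread, weighting the tissues by their spread and the count of splits at an unadjusted p were chosen after.

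An animal stood apart from the other 3 in 4 of 119 groups of 4 animal values tested, where chance marks about 1 in 20 groups. Asap1 in brain was at −0.38 in animal 2 and between −2.90 and −2.58 in the others, whose means hold floor values. Ift81 in muscle was at −0.56 in animal 4 and between −0.30 and −0.26 in the others. Spire1 in pancreas was at 0.13 in animal 4 and between 0.50 and 0.55 in the others. Cat in muscle was at −0.53 in animal 3 and between −0.22 and −0.21 in the others.

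Of 16 groups of 8 arrays, 3 held an array far from the rest. The brain array of animal 4 with the knockout in Cy3 had 20280 values, against 20530 to 20607, and a spread (median absolute deviation) of 0.491, against 0.126 to 0.279. The muscle array of animal 4 with the knockout in Cy5 had a median of −0.045, against −0.018 to −0.002. Without the brain array of widest spread, and so without animal 4 in brain, brain and muscle differed in 0 genes instead of 75.

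In the fit with a shared spread, limma called 75 genes between brain and muscle, 2 between kidney and muscle and 94 between muscle and pancreas; with the animal as a block the counts were 0, 0 and 24, and with only the 2 tissues fitted 0, 0 and 0. For brain and muscle 1 of the 35 splits of the 8 animal values gave as many, the real one, with at most 1 call in any other. For kidney and muscle it was also 1 of the 35, with 2 calls against at most 1. For muscle and pancreas it was 1 of the 35, with 94 calls against at most 39, but by the number of genes at an unadjusted p under 0.05 (2080, highest other 2200) 3 of the 35 were as large. The same animals gave both tissues, and only 8 splits exchange the tissues within every animal, too few for a share under 0.05; among them the highest other gave 0 calls for brain and muscle, 0 for kidney and muscle and 4 for muscle and pancreas. For brain and kidney (0 calls, highest other 1), brain and pancreas (0, highest other 2) and kidney and pancreas (0, highest other 0), 35 of the 35 splits give as many by construction, which says nothing about chance. The splits do not test unequal spreads of the tissues. Nor do they test a deviation of the wild-type pool in a tissue, which all its animals share and which could set the real split apart.

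The gene differences marked by the test were Ttll6 0.51, Psmd2 −1.21, Man1c1 −1.39, 2310030G06Rik −1.24, Ublcp1 −1.36 and Trerf1 −0.54 for brain minus muscle, and Psmd2 −1.12 for kidney minus muscle. For muscle minus pancreas they were Cnn2 1.12, Man1c1 1.64, Psmd2 1.04, Ublcp1 1.38, Bace2 1.58, Tulp2 −0.67, Pomc −0.63, Homez −0.74, Best1 −0.66 and Tsen15 −0.74.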

How the results depend on the processing

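Floor values as missing, weights for the spread of each tissue and the loss of the brain array of widest spread were chosen after seeing the data. Leaving floor values out of the orientation rule was likewise not part of that rule as fixed, which kept them. The other settings were fixed before. The cause of a change was not tested unless it is given here.

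The 0 calls of brain became 1 with the Cy3 arrays turned and 1 with only the knockout in Cy5, and 0 to 1 without each animal. The 0 calls of kidney became 1 with floor values as missing, 1 with robust moderation and 7 with 8 arrays and a dye term, a fit that takes the arrays of an animal as further values. The 0 calls of muscle became 328 (turned, 74 higher and 254 lower), 1 (only Cy3), 255 (all 4 tissues in 1 fit, 227 higher and 28 lower) and 2 (8 arrays), and 0 to 1 without each animal. The 0 calls of pancreas became 2388 (turned, 1038 higher and 1350 lower), 1 (only Cy5) and 57 (all 4 tissues in 1 fit, 31 higher and 26 lower).

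Without each animal the counts were 0 to 1 for brain and kidney, 0 to 223 for brain and muscle, 0 to 7 for brain and pancreas, 0 to 44 for kidney and muscle, 0 to 3 for kidney and pancreas and 1 to 115 for muscle and pancreas. The 75 calls of brain and muscle became 16 (scaled), 1 (turned), 114 (floor values missing), 147 (each probe by itself), 1 (only Cy5), 2 (only Cy3), and 0 with the replicate block, with only the 2 tissues and without the brain array of widest spread. The 2 calls of kidney and muscle became 0 when scaled, turned, with animals of 1 array kept, with only Cy5, with only Cy3, with the replicate block and with only the 2 tissues, and 17 with weights. The 94 calls of muscle and pancreas became 0 (scaled), 5 (turned), 151 (floor values missing, holding all 94), 54 (animals with 1 array kept), 191 (only Cy5), 13 (only Cy3), 24 (replicate block), 0 (only the 2 tissues) and 0 (weights). The 0 calls became, turned, with only Cy5 and with only Cy3, 1510, 603 and 18 for brain and pancreas and 355, 131 and 3 for kidney and pancreas. The replicate block changed no call of the 3 pairs with 0 calls. If the deposited ratios run the same way, a dye effect no longer cancels with the signs turned, and within 1 orientation it never does.

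For brain and kidney, brain and muscle, brain and pancreas, kidney and muscle, kidney and pancreas, and muscle and pancreas in this order, the r across genes was 0.229, 0.242, 0.187, 0.294, 0.288 and 0.296 with only Cy5, 0.272, 0.124, 0.175, 0.318, 0.341 and 0.305 with only Cy3, and 0.453, 0.352, 0.305, 0.530, 0.528 and 0.530 turned. With floor values as missing it was −0.134 for brain and muscle and 0.0478 for kidney and pancreas. Without each animal it ran from −0.0164 to 0.0692 for kidney and muscle, −0.0258 to 0.0386 for kidney and pancreas and −0.0953 to −0.0139 for muscle and pancreas.

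With the Cy3 arrays turned, brain minus muscle reversed to 0.037 for Psmd2, 0.24 for Man1c1, 0.0886 for 2310030G06Rik, 0.29 for Ublcp1 and 0.0089 for Trerf1, and muscle minus pancreas to −0.22 for Cnn2, −0.13 for Man1c1, 0.88 for Tulp2 and 0.0884 for Pomc; with only Cy5 Tulp2 was 0.21. Other values of genes named between tissues held their call in 125 cases and lost it in 142. Of the 123 values of genes named in a tissue, 109 moved by at least the SD between animals with the Cy3 arrays turned. Many of these genes were picked for a small p and the same sign in both dye orientations. That choice made such a move likely, so the 109 says little about them. The number that moved was 47 when scaled, 47 with only Cy5 and 46 with only Cy3. Over all alternatives 254 moved, 35 passed the test and 1666 did neither. The orientation rule gave 6 of 16 with floor values left out, and 3 with floor values kept, as the rule was fixed. List calls stayed at 0 in all 12 alternatives run. Centring and scaling moved the median of a tissue by at most 0.01. The Nox4 log ratio has no value under any alternative fixed beforehand, since no probe names the gene.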

Other observations

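The test of Hikeshi in the other tissues was set before their values were seen; the count of chance combinations for Hikeshi, the tests of the genes higher on all muscle arrays and those of the dye were chosen after the result was seen.

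Several marker genes of vessels and fibres stood apart in muscle as values that did not pass. Tek and Cdh5, a receptor and a cadherin of endothelial cells, were at 0.60 ± 0.14 (SE, n = 4) and 0.42 ± 0.10, above 0 in all 4 animals, while 11 of 17 endothelial markers lay below 0. Tnni1, slow troponin I, was at 0.72 ± 0.20 and the oxygen store Mb at −0.36 ± 0.14; 9 of 14 slow fibre genes were below 0. The fast fibre calcium buffer Pvalb was at −0.19 ± 0.08, with 9 of 15 fast fibre genes below 0. Usp2, a deubiquitinase of the circadian output, was at 0.80 ± 0.18, and the ribosomal protein gene Rps19 at −0.49 ± 0.13. Hmox2, a haem oxygenase, was at 0.31 ± 0.12 in muscle and −0.35 ± 0.13 in brain.

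In brain the oligodendrocyte genes Cnp and Olig2 were at −0.16 ± 0.07 (SE, n = 4) and −0.10 ± 0.05, below 0 in all 4 animals, with 6 of 11 markers below 0. Gpx1, a glutathione peroxidase, was at −0.50 ± 0.21 and the insulin receptor Insr at 0.32 ± 0.14. In kidney the immediate early gene Junb was at −0.15 ± 0.04, in a list with 15 of 21 genes below 0, the peptide transporter Tap1 at −0.19 ± 0.04, the collagen Col6a2 at −0.17 ± 0.04 and the enkephalin precursor Penk at −0.34 ± 0.09. In pancreas Pnliprp2, a lipase of acinar cells, was at −0.18 ± 0.08, Slc2a2, the glucose transporter of beta cells, at 0.14 ± 0.08, Cxcl10, a chemokine, at −0.24 ± 0.09 and Etfa, of fatty acid oxidation, at 0.29 ± 0.10.

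Hikeshi had a mean of −0.35 ± 0.04 in kidney, without passing the test over all genes, and lies near the targeted Nox4 gene. A change of the DNA carried on the chromosome would be likely to act wherever Hikeshi is transcribed, but it lay below 0 by more than its SE in 0 of the 3 other tissues (0.05 in brain, 0.07 in muscle and 0.02 in pancreas). The differences from kidney were 0.40 ± 0.07, 0.43 ± 0.12 and 0.38 ± 0.16. Their SEs come from the separate tissue fits, for a gene picked by its kidney value. Chance stays open: a p as small arose in 0.58% of 10000 random sets of 22 kidney genes, and 0.295 of the 156 combinations of list and tissue would be expected to hold such a value, each taken with its own gene number (4 to 58) and the p values of its own tissue. The fit of all 4 tissues did not call Hikeshi between kidney and any other tissue. An effect of the knockout in kidney alone was thus not shown, and it stays open.

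The 251 genes higher on all 8 muscle arrays had a median of 0.60 and a median pairwise r of 0.554 over those arrays, with animal medians of 0.28, 0.89, 0.45 and 0.72. Of their 300 probes, 28.3% lay in the last 10% of the probe numbers, a share that 0% of random sets of probes reached. Those sets drew probes independently, although these genes correlate. Only probe numbers were used, not positions on the array, so a place effect may contribute but was not shown. The median of that whole region in muscle lay 0.01 above the rest (SD 0.03, n = 4), higher in 2 of 4 animals. Floor values do not enter the means of these genes, as 0% of these probes held 1 on a muscle array. The choice of genes above 0 on all 8 arrays largely fixed this, since floor values with the knockout in Cy3 were all negative. Only the positive ones, on arrays with the knockout in Cy5, could have occurred, so this is a weak test of spots with 1 channel at the floor. An effect of the knockout in muscle stays open. All 8 arrays were set against the wild-type pool, which counts as 1 control sample. A deviation of that pool would move all 8 arrays together, and the design cannot tell it apart from the knockout. RNA of another cell type stays open as well. The highest median of a marker list in muscle was 0.0758 (podocytes and juxtaglomerular cells, 3 members above 0 and 2 below, SD 0.34). Tek (0.60), Cdh5 (0.42) and Ncam1 (0.48) lay above 0 in all 4 animals. In their lists, however, 11 of 17 endothelial markers and 6 of 10 markers of muscle regeneration and denervation lay below 0. Of the calls between tissues, 63 of 75 for brain and muscle, 2 of 2 for kidney and muscle and 53 of 94 for muscle and pancreas belong to these genes.

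Ratios often changed sign with the dye. The part that does so was shared between tissues at r of at least 0.545, consistent with a dye effect of each probe, which cancels in the mean of both orientations if all ratios run the same way. Deposited ratios of the swapped arrays left unturned would leave a shared dye effect in the part that keeps its sign, which reached r of at most 0.0780 between tissues. This reading stays open, however, since the residuals of an animal's 2 arrays correlated below those of other animals in 10 of 16 combinations and in all 4 kidney animals (−0.438 against 0.207 in animal 2), the sign that unturned ratios would give. Floor values were positive with the knockout in Cy5 and negative with it in Cy3. If every ratio runs knockout over pool, the floor then lies in the Cy3 channel of all arrays. If all ratios run Cy5 over Cy3, with the swapped arrays left unturned, it lies in the channel of the pool on all arrays. Each reading is uniform, so the floor values do not decide between them.

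Turning the signs of whole animals gives 8 patterns per tissue, too few for a share under 0.05. The animals of a tissue also share the wild-type pool, and a deviation of the pool would raise the count of the unturned pattern too. The count of genes at an unadjusted p under 0.05 was 1562 in kidney against at most 1142 in other patterns, 1215 against 782 in muscle, 691 against 720 in brain and 477 against 779 in pancreas.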
